A study of Mus musculus with 13 samples.

How the data were processed

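Lungs of male C57Bl/6 mice given bleomycin or saline were collected at day 21, fixed in formalin and embedded in paraffin, and RNA was extracted from 10 µm sections with an RNeasy FFPE kit, per the labels. Libraries were made from 8 ng of RNA with the SMARTer Stranded Total RNA-Seq Pico kit, which keeps non-polyadenylated RNA. The 13 libraries comprise 8 of bleomycin and 5 of saline. The batch labels put bleomycin replicates 1 to 4 in batch 2 and bleomycin replicates 5 to 8 with all saline replicates in batch 1. Beyond the replicate labels, nothing says that each library is a separate animal, so the p-values measure only the spread between these samples.

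The counts were made by the authors with cutadapt 4.4, STAR 2.7.10b and featureCounts 2.0.3 on genome build mm39, per the submitters' processing notes, and were deposited as whole numbers per gene symbol without normalization. The roles of these tools, the strand setting, the use of molecular identifiers and the annotation release are not given in the sources used here. Even numbers made up 78.4% to 86.1% of counts from 1 to 10 in each library, so both reads of a pair appear to be counted, and a count is then not an independent molecule. The authors also deposited a normalized signal per gene, and the submitters' processing notes name DESeq2 1.42.1. Its values equal the count divided by a size factor per library (0.394 to 1.94): all of them gave back whole reads within 0.05. That table held 29723 genes with a summed count of at least 11, and 5 of its symbols had been turned into dates. It served only for an alternative.

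Total counts were 6337147 to 28885129 per library (median 15859315). No pair of libraries of the same treatment was a duplicate: chi-square per degree of freedom was 10.1 to 267 over 38 pairs. Gene types and lengths came from the GENCODE M21 annotation, matched by symbol for 50671 of 54513 symbols and 97% of tested genes, and no coordinates were used because its build differs.

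Genes were kept by edgeR's filterByExpr over the batch and treatment groups (20468 genes), scaled with TMM factors and tested in edgeR 4.0.16 under R 4.3.3 with robust quasi-likelihood fits (glmQLFit, glmQLFTest) and batch and treatment as additive terms. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The biological coefficient of variation was 0.306. All saline libraries are in batch 1, so the treatment effect compares 4 bleomycin with 5 saline libraries, and the batch effect compares 4 with 4 bleomycin libraries. The numbers in the library names form separate runs for batch 1 bleomycin, saline and batch 2 bleomycin. What these numbers stand for is not given. If they mark separate sets of samples, a set difference within batch 1 cannot be told apart from treatment. Levels are CPM from the TMM-scaled totals. Groups that do not overlap arise by chance for 1.59% of genes with 4 against 5 libraries.

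The 46 gene lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, beside camera with an estimated correlation and fry, over lists with at least 5 tested members. Fry's mixed test, which asks for change in either direction, passed 39 lists. The level of a list is the mean log2 CPM (prior count 2) of its tested members. Levels were compared within batch 1 by exact two-sided permutation over 126 splits. Relations between the matrix list and 7 other lists were computed over the 8 bleomycin libraries after centring within batch, with exact two-sided permutation over 40320 pairings. Each family of tests was adjusted by Benjamini-Hochberg.

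The rule for named genes took the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM, no overlap between batch 1 groups and a symbol that is not a predicted model or an antigen receptor segment. It added up to 4 members of each list by lowest p, 13 fibrosis, epithelial and response genes whatever their value, the 5 largest rises and 5 largest falls by batch, and up to 3 most abundant members of the lists for other tissues, blood and mitochondria. The groups, tests, lists, rule and alternatives were chosen before the data were examined, except for clock genes, short RNA classes, the tests of mitochondrial genes near 0, immunoglobulin segments, the 12 largest protein-coding falls and the alternatives named as later choices.

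Each test was tried on simulated counts with the real means and library sizes and 200 changed genes. For treatment, edgeR recovered 10.4% of 67 genes changed 1.5-fold, 37.3% of 67 changed 2-fold and 87.9% of 66 changed 4-fold over 20468 genes, with 4 false calls (4.26% of calls). For batch it recovered 4.48%, 41.8% and 89.4%, with 2 false calls (2.17%). DESeq2 gave more false calls, 21 for treatment (16% of its calls) and 22 for batch (17.1%). Limma-voom gave 4 (4.21%) and 1 (1.14%). The adjustment is stricter with few changed genes, and the data gave 6319 calls for treatment. Recovery in the data can therefore be higher than in this run. For lists, a separate run changed all genes of 3 lists by 2-fold in place of the 200 genes. Camera recovered 3 of 3 changed lists with 0 false calls among 41. Simulated genes were drawn independently, so this run does not test camera under correlation between the genes of a list. In the data the estimated correlation reached 0.817 (heart muscle list). The exact permutation of levels recovered 0 of 3 with 0 false calls, since few changed lists cannot reach an adjusted p under 0.05 with 126 splits.

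The alternatives were RLE size factors, no low-count filter, a filter of at least 1 CPM in 4 libraries, DESeq2 1.42.0, limma-voom with quality weights, limma on the deposited normalized signal (log2 with a pseudocount of 1), no batch term, batch 1 alone, a replicate block, removal of mitochondrial, haemoglobin and immunoglobulin genes, a fold threshold, list alternatives, each library left out in turn, and bleomycin replicate 8 moved to saline. Protein-coding genes alone, halved counts and pairings exchanged within batch only were later choices. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out of the main comparisons. Some genes that the naming rule selects are not reported here.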

Results

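Total RNA was sequenced in 13 libraries from formalin-fixed, paraffin-embedded lungs of male C57Bl/6 mice, 7 to 8 weeks old, at 21 days after bleomycin or saline. Bleomycin is a DNA-damaging chemotherapy drug that injures the alveoli and is widely used to model lung fibrosis in mice. The bleomycin group held 8 libraries, with replicates 1 to 4 in batch 2 and replicates 5 to 8 in batch 1, and the saline group held 5 libraries, all in batch 1. Each library was made from 8 ng of RNA out of a 10 µm section. Total counts ranged from 6337147 to 28885129 (median 15859315), and 22801 to 29325 genes per library had at least 1 count. The batch 2 bleomycin libraries were the shallowest as a set, with 6337147 to 12982422 counts, against 21727502 to 28885129 in batch 1 bleomycin and 9527580 to 26043735 in saline.

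Bleomycin replicate 8 carries conflicting labels, a title that says control against a treatment label and a library name that say bleomycin, and it was kept in the bleomycin group. It held 8202 CPM (counts scaled by library total and normalization factor) of Fn1, where the other bleomycin libraries held 1714 to 8078 and the saline libraries 369 to 450.1. Its Spp1 level was 910.5 CPM, against 275 to 838 in other bleomycin libraries and 20.5 to 38.1 in saline. Col1a1 stood at 3982 CPM in it, against 928 to 4061 and 215 to 324. With this library moved to saline, 645 genes passed in place of 6319.

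The comparison of bleomycin with saline asks which genes differ in the lung 3 weeks after the drug. Genes of fibrosis and inflammation were among those that rose. Fn1, which encodes the matrix glycoprotein fibronectin, went from 406 ± 33.8 CPM in saline to 4928 ± 2792 CPM in batch 1 bleomycin libraries (log2 change 3.60, SE 0.46, adjusted p = 0.000205). Spp1, which encodes osteopontin, went from 28.8 ± 7.43 to 557 ± 286 CPM (4.27, SE 0.41, adjusted p = 3.21e-05). Col1a1, a chain of type I collagen, went from 276 ± 41.1 to 2593 ± 1302 CPM (3.23, SE 0.41, adjusted p = 0.000173). In the batch 2 bleomycin libraries these genes stood at 4307 ± 2546, 509 ± 223 and 2371 ± 1144 CPM. Levels here and below are means ± SD over 5 saline and 4 batch 1 bleomycin libraries (4 for batch 2 where given), and changes with their SE and Benjamini-Hochberg adjusted p come from edgeR's quasi-likelihood test.

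In all, 6319 of 20468 tested genes changed, 3586 higher and 2733 lower in bleomycin, and 3036 of them by at least 2-fold (1603 higher, 1433 lower). The balance of directions depended on the method, with 3433 higher and 3512 lower by DESeq2, 3166 and 3028 with RLE size factors, 2954 and 2834 in batch 1 only, and 4043 and 2923 by limma-voom. The 12 largest rises among abundant, named genes were those of Mmp12, Saa3, Adamts4, Cemip, Lama1, Ptx3, Timp1, Spp1, Slc26a4, Ccl2, Tnc and Fn1. Mmp12, an elastase of macrophages, had the largest fitted change (1.03 ± 0.66 to 85.5 ± 45.1 CPM, log2 change 6.21, SE 0.82, adjusted p = 0.000305). Saa3, an acute-phase gene, spread widely among bleomycin libraries (25.4 ± 30.4 CPM, log2 change 5.70, SE 1.41, adjusted p = 0.0117), and it did not pass by limma-voom (adjusted p = 0.146). Adamts4, a protease of proteoglycans, rose by 5.69 (SE 0.71) and Cemip, a hyaluronan-degrading protein, by 5.35 (SE 0.79). Lama1, a laminin chain, rose by 4.43 (SE 0.35), and Ccl2, a monocyte chemokine, by 4.00 (SE 0.72). Of the 12 largest falls, 10 were mitochondrial transfer RNAs, described with the other short RNAs below, and the others were Ankrd63 (log2 change -3.58, SE 0.43) and the 5S ribosomal RNA copy n-R5s210 (-3.53, SE 0.73). Batch 2 holds no saline library, so the change is estimated within batch 1 and batch 2 adds only to the estimate of spread. Within batch 1 the library names number bleomycin and saline in separate runs, so a set difference there cannot be told apart from treatment.

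**Figure D1:**
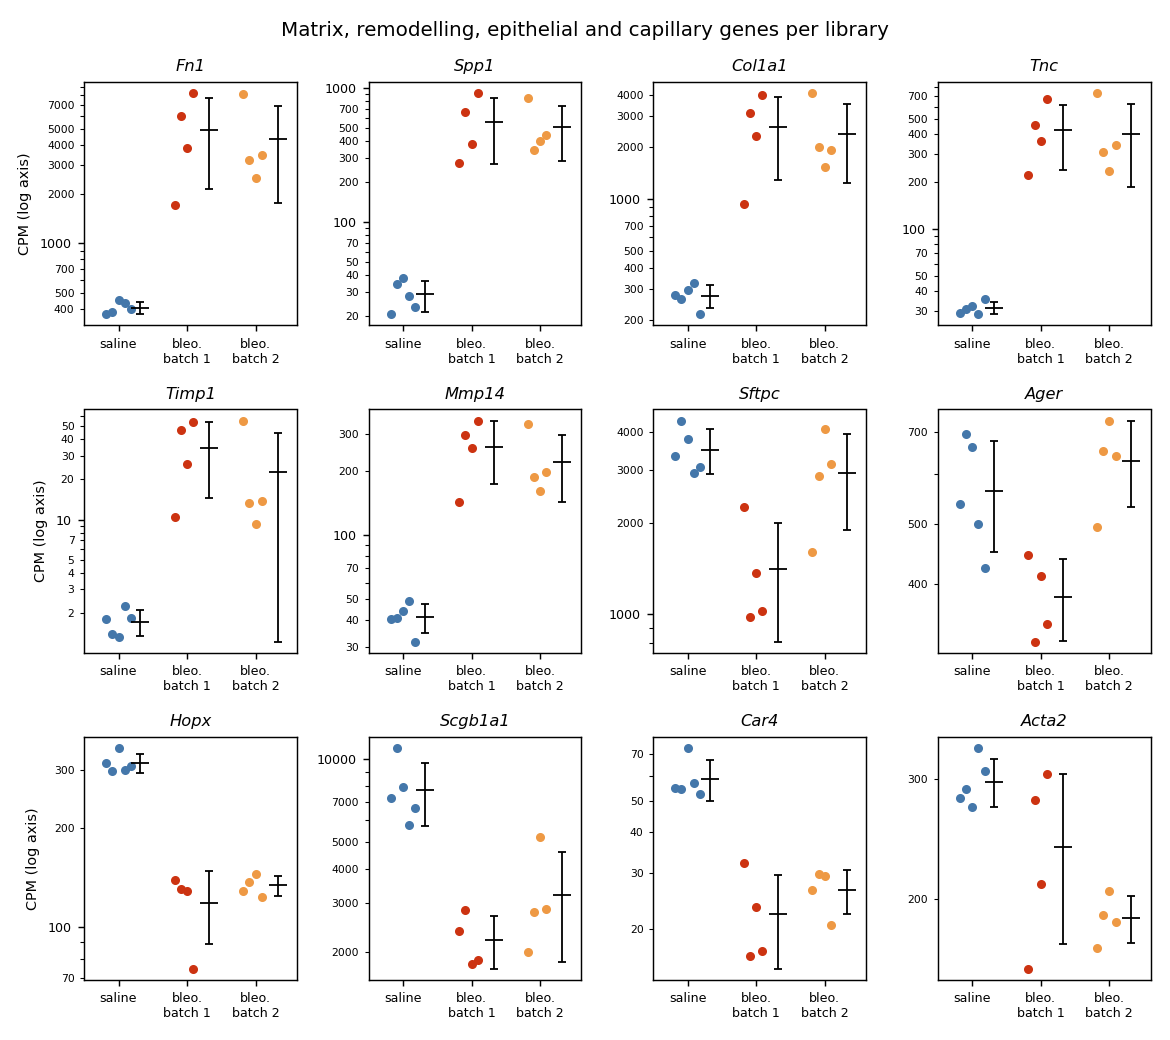
CPM of 12 genes (log axis) in each saline (blue), batch 1 bleomycin (red) and batch 2 bleomycin (orange) library, with the mean ± SD of each set in black. Fn1, Spp1, Col1a1, Tnc, Timp1 and Mmp14 lie above every saline library in all 8 bleomycin libraries, whereas Sftpc and Ager lie lower in batch 1 (1410 and 382 CPM on average) than in batch 2 (2919 and 630 CPM), against 3501 and 565 CPM in saline.

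Gene groups were tested as 46 fixed lists of cell type markers and processes. Camera with its preset correlation placed 22 lists higher and 10 lower in bleomycin, but with an estimated correlation 0 of 46 passed, the lowest adjusted p being 0.0868. Of 100 splits of the batch 1 libraries, 18, the real split included, gave as many lists, so chance is not excluded for their number. All the others of these 18 keep 0, 1 or 3 of the 4 bleomycin labels. They therefore carry much of the real contrast or its reverse and are no clean test of chance. Splits that keep 2 of the labels gave 2 to 24 lists. Fry, which asks whether a list's genes move on balance in a single direction, passed 30 lists. The exact two-sided permutation test of list levels within batch 1 passed 30 lists, 22 higher and 8 lower. The smallest p that its 126 splits allow is 0.00794 (adjusted p = 0.013). All 32 lists called by camera reached that smallest exact permutation p except alveolar type 2 (adjusted p = 0.0365), cholesterol and fatty acid synthesis (0.0252), club and goblet (0.0685) and mitochondrial genome (0.0589).

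**Figure D2:**
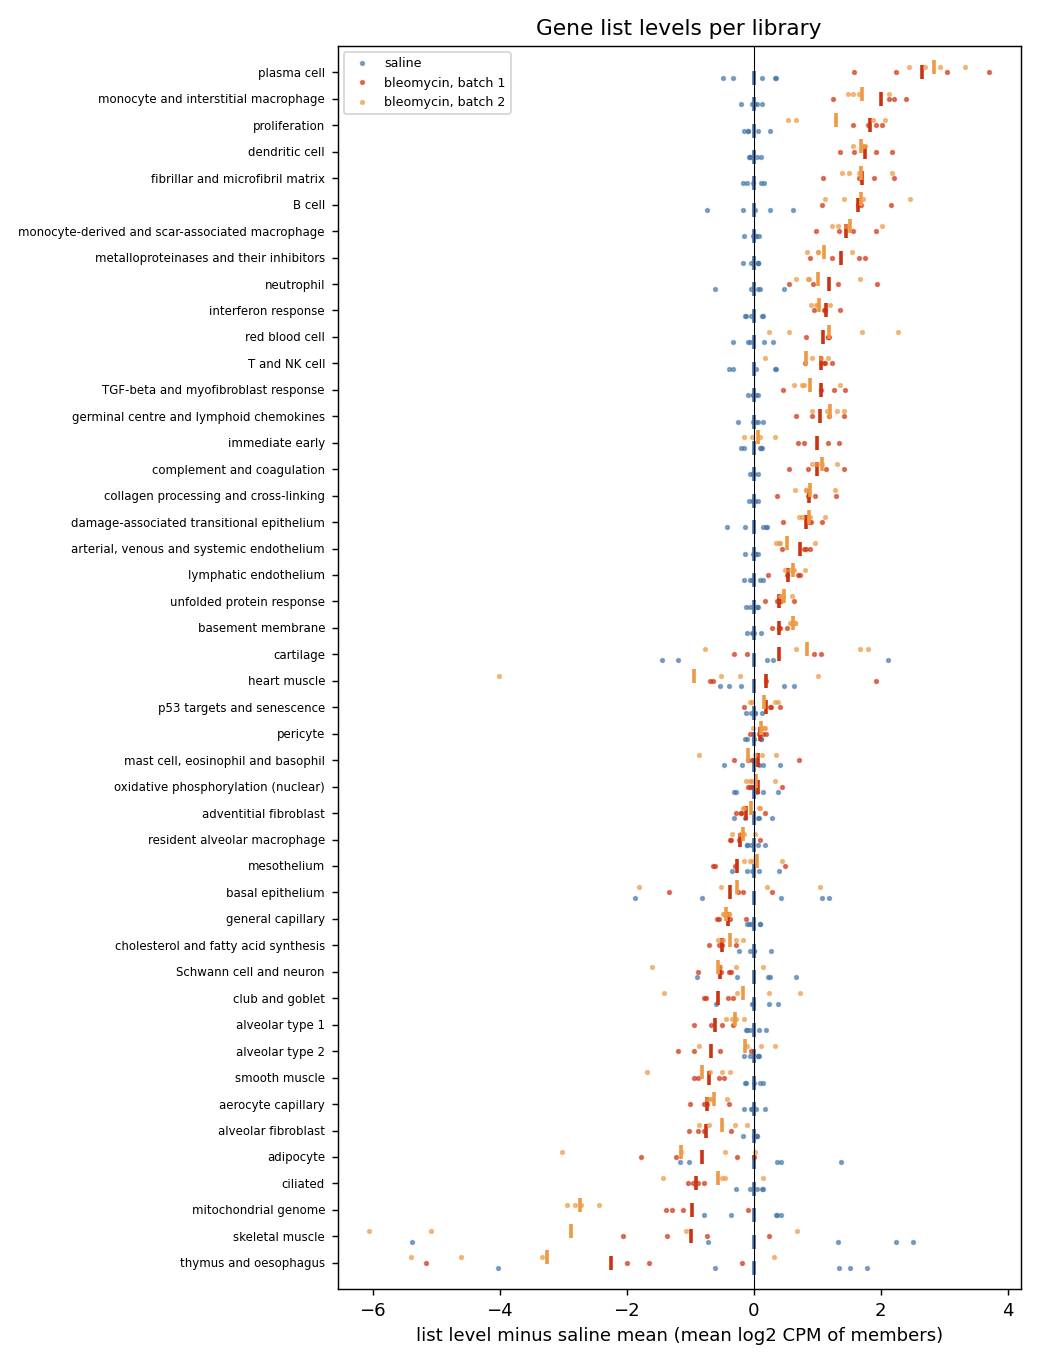
Level of each of the 46 gene lists per library (mean log2 CPM of its tested members) minus the saline mean, with points for single libraries and vertical bars for the means of saline (blue), batch 1 bleomycin (red) and batch 2 bleomycin (orange). The plasma cell list lies highest, 2.65 above saline in batch 1 and 2.85 in batch 2, and the alveolar fibroblast, ciliated and aerocyte capillary lists lie below saline.

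Genes of the extracellular matrix rose together. Of 35 genes for fibrillar collagens, elastic fibres and related glycoproteins, 30 rose and 0 fell (30 adjusted over the list alone), and the list's median log2 change was 1.60 (camera adjusted p = 5e-23; adjusted p = 0.157 with an estimated correlation). Eln, which encodes elastin, went from 143 ± 22.4 to 1552 ± 543 CPM (log2 change 3.44, SE 0.28), and Cthrc1, a marker of matrix-producing fibroblasts, from 1.15 ± 0.44 to 11.2 ± 4.81 CPM (3.32, SE 0.37). Col3a1 rose by 2.68 (SE 0.27) and the adhesion-modulating glycoprotein Tnc by 3.77 (SE 0.38). Among 24 genes for collagen processing and cross-linking, 17 rose and 0 fell (19 and 2 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation), among them the cross-linking enzyme Loxl1 (1.58, SE 0.15) and the collagen chaperone Serpinh1 (0.96, SE 0.13). In the basement membrane list 11 of 20 genes rose and 1 fell (11 and 2 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), with Col4a1 at 1.67 (SE 0.18). Of 22 tested metalloproteinases and inhibitors, 15 rose and 1 fell (15 and 2 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). Mmp2, a gelatinase, rose by 2.06 (SE 0.14), the membrane-bound Mmp14 by 2.66 (SE 0.26), and the inhibitor Timp1 from 1.72 ± 0.38 to 34.5 ± 19.9 CPM.

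The TGF-β and myofibroblast list, made of ligands, receptors and response genes of the main fibrogenic pathway, had 22 of 28 genes higher and 0 lower (23 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation). Tgfb1 rose from 38.4 ± 4.15 to 68.3 ± 9.54 CPM (log2 change 0.83, SE 0.12) and Ltbp2, a matrix protein related to the TGF-β binding proteins, by 2.88 (SE 0.28). Ccn2, a TGF-β target, rose by 1.03 (SE 0.36, adjusted p = 0.0481), but it passed with a library left out only without bleomycin replicate 1 or 5, and the 11 other left-out libraries gave adjusted p 0.0542 to 0.164. Acta2, the smooth muscle actin used to mark myofibroblasts, did not pass (297 ± 24.3 against 238 ± 67.0 CPM, log2 change -0.32, SE 0.15, adjusted p = 0.117). Acta2 was lower in 7 alternatives. Among them were the fits without bleomycin replicate 8 (-0.49, adjusted p = 0.0194), by DESeq2 (-0.37, 0.0492) and by limma-voom (-0.36, 0.0276). Others were those on the deposited normalized table (-0.41, 0.0409) and with protein-coding genes only (-0.38, 0.0457). The rest mix batch with treatment: without the batch term (-0.48, 0.0149) and under the replicate block (-0.72, 0.000974). The smooth muscle list, which shares contractile genes with myofibroblasts, was lower: 5 of 12 fell and 0 rose (6 adjusted over the list alone; adjusted p = 0.302 with an estimated correlation), with Cnn1 at -1.18 (SE 0.24) and Synpo2 at -0.54 (SE 0.15).

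Markers of resident stromal cells were mixed. In the alveolar fibroblast list 11 of 16 genes fell and 3 rose, the same counts when adjusted over the list alone (adjusted p = 0.287 with an estimated correlation). Inmt, a methyltransferase, dropped by 2.53 (SE 0.37) and Itga8, an integrin, by 1.13 (SE 0.13), while Cdh11, a cadherin of activated fibroblasts, rose by 1.26 (SE 0.13). The adventitial fibroblast list was not called (3 of 14 higher, 3 lower, the same adjusted over the list alone; adjusted p = 0.601 with an estimated correlation). Its members split, with Col15a1 up by 1.69 (SE 0.31) and Igfbp6 down, from 70.6 ± 13.6 to 15.6 ± 5.27 CPM. In the pericyte list 3 of 12 rose and 1 fell, the same adjusted over the list alone (adjusted p = 0.926 with an estimated correlation). Postn, a matricellular gene, was at 193 ± 9.09 and 273 ± 60.8 CPM (adjusted p = 0.0122, and 0.0725 without bleomycin replicate 8). The mesothelium list had 1 of 10 higher and 4 lower, also adjusted over the list alone (adjusted p = 0.573 with an estimated correlation), Gpm6a falling by 0.96 (SE 0.18). Without bleomycin replicate 8 camera called the list lower (median -0.81, adjusted p = 0.0188), as it did without genes held by other lists too (-0.63, adjusted p = 0.0345).

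Of the alveolar epithelial lists, type 1 was lower in batch 1 bleomycin by camera, fry and exact permutation, and type 2 by camera and exact permutation but not by fry (adjusted p = 0.0766). In the alveolar type 2 list, the surfactant-producing cells, 6 of 21 genes fell and 0 rose, also adjusted over the list alone (adjusted p = 0.53 with an estimated correlation). Sftpc, a surfactant protein gene, went from 3501 ± 587 to 1410 ± 599 CPM (log2 change -1.31, SE 0.29, adjusted p = 0.00512), and Sftpb from 1089 ± 118 to 699 ± 79.1 CPM (-0.64, SE 0.16). In batch 2 these stood at 2919 ± 1023 and 1061 ± 300 CPM, and the list level was 0.67 below saline in batch 1 (-0.67) and 0.13 below in batch 2 (-0.13). Without the batch term the type 2 call ended (median -0.31, adjusted p = 0.101), as did those of Sftpc (adjusted p = 0.129), Sftpb (0.21) and the type 1 gene Ager (0.583). Under the replicate block, which sets mainly batch 2 bleomycin libraries against saline, the type 2 median and Ager turned positive (both 0.07). In the alveolar type 1 list, the thin gas-exchange cells, 11 of 20 fell and 1 rose (14 and 3 adjusted over the list alone; adjusted p = 0.201 with an estimated correlation). Hopx, a type 1 transcriptional regulator, dropped from 314 ± 21.0 to 118 ± 29.4 CPM and stood at 134 ± 9.59 in batch 2. Ager, a membrane receptor of these cells, was at 565 ± 114 and 382 ± 56.9 CPM (log2 change -0.56, SE 0.15, adjusted p = 0.0104) but at 630 ± 98.9 CPM in batch 2, higher than in batch 1 bleomycin (0.72, SE 0.16, adjusted p = 0.0291).

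Genes of damage-associated transitional epithelium, a state between both alveolar cell types, went the opposite way. Of 20 such genes 12 rose and 0 fell, the same adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). Clu, a secreted chaperone, went from 74.2 ± 4.72 to 240 ± 62.5 CPM (log2 change 1.70, SE 0.14) and the keratin Krt8 from 55.3 ± 6.25 to 94.4 ± 24.8 CPM (0.77, SE 0.14). Among airway epithelial lists the ciliated list was lower by camera, fry and exact permutation, and the club and goblet list by camera alone (fry adjusted p = 0.0766). In the ciliated list 17 of 20 fell and 0 rose, the same adjusted over the list alone (adjusted p = 0.21 with an estimated correlation), with Tppp3 at -1.63 (SE 0.23) and the ciliary gene Hydin at -1.32 (SE 0.23). In the club and goblet list, secretory airway cells, 7 of 18 fell and 1 rose (9 and 1 adjusted over the list alone; adjusted p = 0.509 with an estimated correlation). Scgb1a1, the main club cell secretory protein, dropped from 7713 ± 2006 to 2211 ± 479 CPM, while Retnla, also a macrophage gene, rose by 2.67 (SE 0.43). The basal epithelium list was not called (1 of 10 higher, 0 lower, and 0 adjusted over the list alone; adjusted p = 0.908 with an estimated correlation). Its exception Krt17 (0.70 ± 0.52 to 2.22 ± 0.95 CPM) had adjusted p = 0.0729 without bleomycin replicate 6 and 0.056 without bleomycin replicate 7.

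Endothelial lists moved in opposite directions. Capillary genes fell: in the general capillary list 8 of 15 were lower and 3 higher (9 and 3 adjusted over the list alone; adjusted p = 0.207 with an estimated correlation). In the list of aerocytes, the capillary cells specialised for gas exchange, 11 of 15 were lower and 1 higher, the same adjusted over the list alone (adjusted p = 0.158 with an estimated correlation). Epas1, a hypoxia-responsive transcription factor, went from 3514 ± 360 to 1866 ± 178 CPM (log2 change -0.91, SE 0.11) and Car4, a carbonic anhydrase of aerocytes, from 58.6 ± 8.44 to 22.3 ± 7.26 CPM (-1.39, SE 0.19). Among arterial, venous and systemic endothelial genes 13 of 20 rose and 4 fell, the same adjusted over the list alone (adjusted p = 0.173 with an estimated correlation). Vcam1, a leukocyte adhesion molecule, rose by 1.26 (SE 0.13) and the Notch target Hey1 fell by 1.39 (SE 0.16). In the lymphatic list 5 of 9 rose and 1 fell (7 and 1 adjusted over the list alone; adjusted p = 0.181 with an estimated correlation), with the lymphatic transcription factor Prox1 up by 1.75 (SE 0.17). This call ended without the genes held by other lists too (adjusted p = 0.0507), and Ccl21a (1.35, SE 0.15) is uncertain because near-identical gene copies exist.

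Myeloid markers were among the groups that rose most. In the monocyte and interstitial macrophage list 23 of 24 genes rose and 0 fell, the same adjusted over the list alone, with a median log2 change of 2.21 (camera adjusted p = 2.09e-29; adjusted p = 0.0868 with an estimated correlation). Ms4a7, a macrophage membrane protein, went from 3.01 ± 0.62 to 25.5 ± 3.96 CPM (3.09, SE 0.19, adjusted p = 1.34e-07), and C1qc, a complement chain made by macrophages, from 11.8 ± 2.01 to 76.1 ± 22.9 CPM. In the list of monocyte-derived and scar-associated macrophages 16 of 24 rose and 1 fell, also adjusted over the list alone (adjusted p = 0.134 with an estimated correlation), including Cd68 (1.75, SE 0.16) and Apoe (2.32, SE 0.24). Resident alveolar macrophage genes split, 5 of 20 higher and 5 lower (7 and 5 adjusted over the list alone; adjusted p = 0.926 with an estimated correlation), and their median and mean were negative (-0.20 and -0.21) where camera's direction was up. Itgax rose by 1.97 (SE 0.15), while Krt79 fell from 5.19 ± 1.60 to 0.68 ± 0.19 CPM. Dendritic cell genes had 15 of 18 higher and 0 lower (16 adjusted over the list alone; adjusted p = 0.0868 with an estimated correlation), such as the antigen-presentation gene H2-Ab1 (1.76, SE 0.14) and Fscn1 (2.88, SE 0.22). Neutrophil genes had 6 of 13 higher and 0 lower, also adjusted over the list alone (adjusted p = 0.21 with an estimated correlation), led by Lcn2 (26.2 ± 5.59 to 112 ± 19.9 CPM), which injured epithelium also expresses. The mast cell, eosinophil and basophil list, with 7 of 15 genes tested, was not called (1 higher, Siglece, and 1 lower, Gata2, also adjusted over the list alone; adjusted p = 0.908 with an estimated correlation), and its median was 0.13 where camera's direction was down.

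Lymphoid lists rose as well. In the plasma cell list, antibody-secreting cells, 14 of 19 genes rose and 0 fell (15 and 1 adjusted over the list alone; adjusted p = 0.158 with an estimated correlation). Jchain, the joining chain of secreted antibodies, went from 9.87 ± 3.93 to 97.4 ± 42.3 CPM and Igha, the IgA heavy chain, from 6.12 ± 3.12 to 66.3 ± 23.0 CPM. B cell genes had 15 of 16 higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.201 with an estimated correlation), among them Bank1 (8.84 ± 2.63 to 26.1 ± 6.02 CPM). In the T and NK cell list 11 of 26 rose and 1 fell (14 and 1 adjusted over the list alone; adjusted p = 0.173 with an estimated correlation), with Cd4 at 1.93 (SE 0.22) and the cytokine receptor Il7r at 1.89 (SE 0.17). Of 8 tested germinal centre and lymphoid chemokine genes 5 rose and 0 fell, also adjusted over the list alone (adjusted p = 0.134 with an estimated correlation). Cxcl13, the chemokine that attracts B cells, rose from 3.30 ± 1.06 to 27.1 ± 20.7 CPM. That list was not called without the genes it shares with other lists (adjusted p = 0.0945).

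Innate response and cell division genes rose. All 28 proliferation genes rose, also adjusted over the list alone (adjusted p = 0.158 with an estimated correlation), for example the mitotic kinase Cdk1 (1.22 ± 0.05 to 8.95 ± 2.08 CPM) and the replication factor Mcm3 (9.09 ± 1.19 to 24.8 ± 6.24 CPM). Of 24 interferon-response genes 19 rose and 0 fell (20 adjusted over the list alone; adjusted p = 0.0943 with an estimated correlation). Rsad2, an antiviral effector, rose by 2.84 (SE 0.22) and the chemokine Cxcl10 by 3.94 (SE 0.38). Complement and coagulation genes had 15 of 21 higher and 1 lower, also adjusted over the list alone (adjusted p = 0.168 with an estimated correlation), with C4b at 1.57 (SE 0.14) and the exception Thbd, an endothelial anticoagulant receptor, falling by 0.96 (SE 0.12). In the unfolded protein response list 12 of 21 rose and 3 fell, the same adjusted over the list alone (adjusted p = 0.37 with an estimated correlation). The chaperone genes Hspa5 and Calr, of the endoplasmic reticulum, rose by 0.89 (SE 0.13) and 1.10 (SE 0.16). The list of p53 targets and senescence was not called (8 of 24 higher, 2 lower, the same adjusted over the list alone; adjusted p = 0.764 with an estimated correlation). The cell cycle inhibitor Cdkn2b rose by 0.66 (SE 0.13), and Cdkn1a by 0.53 (SE 0.15, adjusted p = 0.0136), which became 0.0525 without bleomycin replicate 8, 0.0568 without bleomycin replicate 7 and 0.104 without the batch term.

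Immediate early genes, which respond within minutes to stress or handling, rose in batch 1. There 14 of 22 rose and 0 fell (15 adjusted over the list alone; adjusted p = 0.168 with an estimated correlation), and the list level stood 1.00 above saline, against 0.07 in batch 2. Fos went from 17.6 ± 3.89 to 56.0 ± 19.5 CPM in batch 1 and was at 19.5 ± 5.35 CPM in batch 2, and 9 of the 22 genes were lower in batch 2 than in batch 1 bleomycin. Some stood above saline in both batches, among them Socs3, a feedback inhibitor of cytokine signalling (16.2 ± 2.94 in saline, 116 ± 44.9 and 58.5 ± 23.2 CPM), Junb (24.8 ± 1.25, 78.3 ± 17.4 and 54.9 ± 11.7 CPM) and Atf3 (5.74 ± 1.53, 21.8 ± 8.50 and 13.7 ± 5.54 CPM). Without the batch term neither the list (median 0.54, adjusted p = 0.0691) nor Fos (1.11, adjusted p = 0.0576) was called.

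Among metabolic lists, cholesterol and fatty acid synthesis was lower, with 10 of 23 genes down and 0 up (11 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation). Sc5d, an enzyme of the late sterol pathway, fell by 0.66 (SE 0.11). Nuclear genes of oxidative phosphorylation were not called (1 of 22 higher, 0 lower, and 0 adjusted over the list alone; adjusted p = 0.955 with an estimated correlation). The exception, Uqcrc1 (0.50, SE 0.16, adjusted p = 0.0315), did not pass without bleomycin replicates 5, 6 or 8 or saline replicates 2, 3 or 5 (adjusted p 0.0534 to 0.0945). In the mitochondrial genome list 6 of 15 genes fell and 0 rose, also adjusted over the list alone (adjusted p = 0.423 with an estimated correlation). Mt-Co2, a cytochrome oxidase subunit, went from 90.9 ± 41.5 to 26.3 ± 9.70 CPM, whereas mt-Co1 was at 3565 ± 831 and 3427 ± 2196 CPM (adjusted p = 0.919). Counts of mt-Co2, mt-Atp6, mt-Co3 and mt-Nd4l are uncertain, since near-identical nuclear copies share over 90% of their sequence.

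Genes of blood and of tissues next to the lung were measured as other possible contents of a section. Of 7 tested red blood cell genes 3 rose and 0 fell (5 adjusted over the list alone; adjusted p = 0.382 with an estimated correlation), with the haem synthesis enzyme Alas2 at 1.63 (SE 0.41) and haemoglobin at 0.003 ± 0.001% of counts in saline and 0.008 ± 0.001% in batch 1 bleomycin. No heart or skeletal muscle gene passed: 0 of 18 heart genes (adjusted p = 0.955 with an estimated correlation) and 0 of 14 skeletal muscle genes (adjusted p = 0.782 with an estimated correlation), also adjusted over the list alone. Their levels varied between libraries, with Ttn at 3992 ± 2985 CPM in saline and 2753 ± 2454 in batch 1 bleomycin. The list of thymus and oesophagus had 0 of 9 changed, also adjusted over the list alone (adjusted p = 0.593 with an estimated correlation). Krt13, a keratin of stratified epithelium, ranged from 0.12 to 1040 CPM among saline libraries. In the adipocyte list 1 of 13 fell, Adrb3 (-1.34, SE 0.31), also adjusted over the list alone (adjusted p = 0.675 with an estimated correlation). The cartilage list had 2 of 10 higher and 0 adjusted over the list alone (adjusted p = 0.908 with an estimated correlation), with a median of -0.12 where camera's direction was up, and its calls were Col11a1 (adjusted p = 0.0396) and Sox9 (adjusted p = 0.0457). Without any of bleomycin replicates 3, 4, 6, 7 or 8 or saline replicates 1, 3, 4 or 5 both calls ended (adjusted p 0.0514 to 0.126 for Col11a1 and 0.0555 to 0.121 for Sox9), and Sox9 also ended without bleomycin replicate 5. In the Schwann cell and neuron list 1 of 13 rose, Mal, and 4 fell, also adjusted over the list alone (adjusted p = 0.593 with an estimated correlation). Skeletal muscle was called lower without saline replicate 2 (median -2.39, adjusted p = 0.0331). The adipocyte list was called lower without bleomycin replicate 8 (-1.14, adjusted p = 0.0261), without saline replicate 3 (-0.96, adjusted p = 0.0302), without saline replicate 5 (-0.94, adjusted p = 0.0393) or without the batch term (-0.86, adjusted p = 0.0329).

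Short non-coding RNAs of 6 classes fell, a grouping made after their values were seen, and microRNA genes did not fall as a class (4 of 46 lower, 0 higher, median log2 change -0.17, with a median level of 0.653 CPM). Over small nuclear, small nucleolar, small Cajal body, ribosomal, mitochondrial transfer and miscellaneous RNAs, 525 of 640 tested genes were lower and 1 higher, with a median log2 change of -2.37, and they made up 19.2% of all genes called lower. All 19 mitochondrial transfer RNAs fell, with a class level of 6.41 ± 1.26 in saline and 3.01 ± 0.87 in batch 1 bleomycin (mean log2 CPM, exact permutation p = 0.0159). Among 381 small nuclear RNA genes, which include near-identical copies whose single counts are uncertain, 303 were lower (1.95 ± 0.98 against 0.08 ± 0.43, exact permutation p = 0.0159). The share of counts in these classes was 4.87 ± 2.63% in saline, 1.45 ± 0.50% in batch 1 bleomycin and 1.51 ± 0.24% in batch 2, and saline replicate 2 held the highest share, 9.45%.

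**Figure D3:**
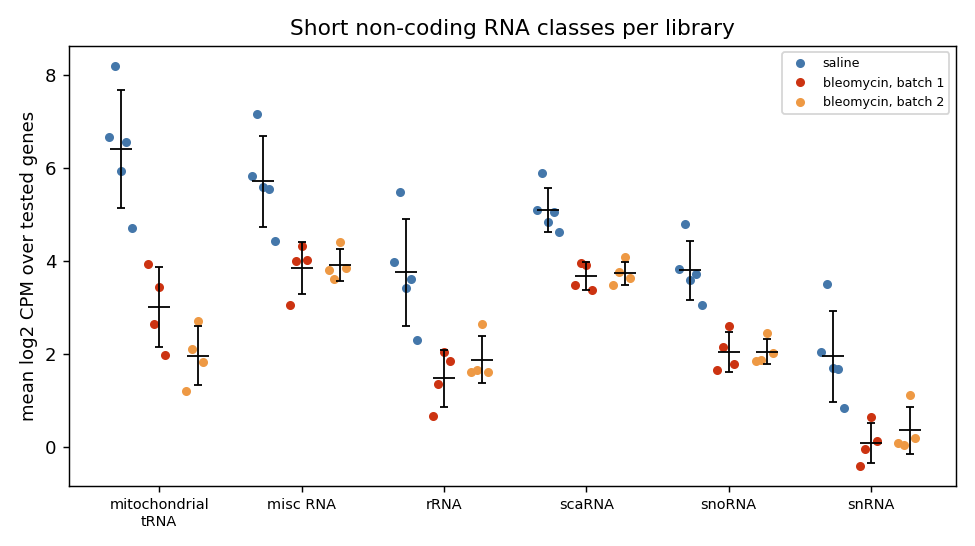
Mean log2 CPM over the tested genes of 6 short non-coding RNA classes in each library, with points for saline (blue), batch 1 bleomycin (red) and batch 2 bleomycin (orange) libraries and the mean ± SD of each set in black. In each of these 6 classes the saline mean lies above both bleomycin means, from 5.10 against 3.68 for small Cajal body RNAs to 6.41 against 3.01 for mitochondrial transfer RNAs in batch 1.

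The comparison of the 4 batch 2 with the 4 batch 1 bleomycin libraries shows how far libraries of the same treatment differed by batch. Matrix genes stood close: Fn1 differed by -0.19 (SE 0.45), Col3a1 by 0.01 (SE 0.27) and 0 of the 35 matrix genes passed. In all, 343 of 20468 genes differed, 112 higher and 231 lower in batch 2, against 737 by DESeq2, 983 by limma-voom and 79 among protein-coding genes only. A split that exchanges only replicates 1 and 5 between the batches gave 660, so chance is not excluded for this count. Protein-coding genes made up 61 of the 112 higher and 84 of the 231 lower genes. Small nuclear RNAs made up 31 of the higher genes, and processed pseudogenes 71 of the lower genes. The largest rises by the rule were those of n-R5s195, a 5S ribosomal RNA copy, Dbp, the signal recognition particle RNAs Rn7s2 and Rn7s1, and Nr1d1. Rn7s2 went from 31.1 ± 6.85 CPM in batch 1 to 189.6 ± 24.6 in batch 2 (log2 change 2.61, SE 0.20, adjusted p = 2.16e-05). It and Rn7s1 are near-identical copies, so their single counts are uncertain, and without the batch term their treatment changes turned positive (1.04 and 0.14). The largest falls were those of mt-Tg, mt-Co3, mt-Co2, mt-Nd4l and Ttyh1. Mt-Co2 went from 26.3 ± 9.70 to 0.63 ± 0.26 CPM (-5.40, SE 0.60). Ttyh1, a membrane protein gene, went from 37.6 ± 21.1 to 1.02 ± 0.68 CPM (-5.05, SE 0.75), against 257 ± 163 CPM in saline. Among saline libraries Ttyh1 and the transfer RNA mt-Tg ran in the same order, both highest in replicate 2 (526 and 4260 CPM). A shared source of their counts was not tested, so the fall of Ttyh1 is uncertain. By limma-voom these falls did not pass (adjusted p 0.108 to 0.461) at folds of near the same size (-8.63 for mt-Tg, -5.80 for mt-Co3, -5.19 for mt-Co2, -4.73 for mt-Nd4l and -5.39 for Ttyh1), and mt-Tg did not without bleomycin replicate 2 (0.0588) or 3 (0.0688), nor n-R5s195 without bleomycin replicate 6 (0.0642). Leaving out single bleomycin libraries moved the count from 148 (without replicate 3) to 1093 (without replicate 8), with 534 without replicate 1, 165 without replicate 2, 183 without replicate 4, 187 without replicate 6 and 197 without replicate 7.

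Dbp and Nr1d1 belong to the circadian clock, so 14 further clock genes were looked at after their values had been seen. Of the 16 genes, 4 were higher in batch 1 bleomycin than in saline and 11 lower, and 12 differed between the bleomycin batches, 2 of them Dbp and Nr1d1, which had been picked for that difference. Dbp, a clock output gene, stood at 99.2 ± 11.8 CPM in saline, 10.3 ± 6.99 in batch 1 bleomycin and 67.6 ± 27.4 in batch 2, and Arntl, a core activator of the clock, at 4.77 ± 1.06, 30.8 ± 7.41 and 11.8 ± 2.74 CPM. The repressor gene Nr1d1 went from 149 ± 26.5 to 33.1 ± 8.91 CPM and stood at 95.6 ± 46.4 in batch 2. Its batch difference (1.53, SE 0.32, adjusted p = 0.0419) did not pass without bleomycin replicates 3, 4, 5, 6 or 7 or saline replicates 3, 4 or 5 (adjusted p 0.0566 to 0.132), by limma-voom (0.0522), with no low-count filter (0.0805), with protein-coding genes only (0.0716) or with bleomycin replicate 8 moved to saline (0.0883). Its fold stayed near in size in these fits (1.27 to 1.73). Without the batch term the treatment change of Dbp did not pass (-1.37, adjusted p = 0.142). Per1, a light-induced clock gene, did not change in the treatment comparison (160 ± 11.1 and 153 ± 24.0 CPM, adjusted p = 0.816). In batch 2 bleomycin libraries, however, Per1 stood at 59.3 to 123 CPM, below every saline library (141 to 168 CPM).

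**Figure D4:**
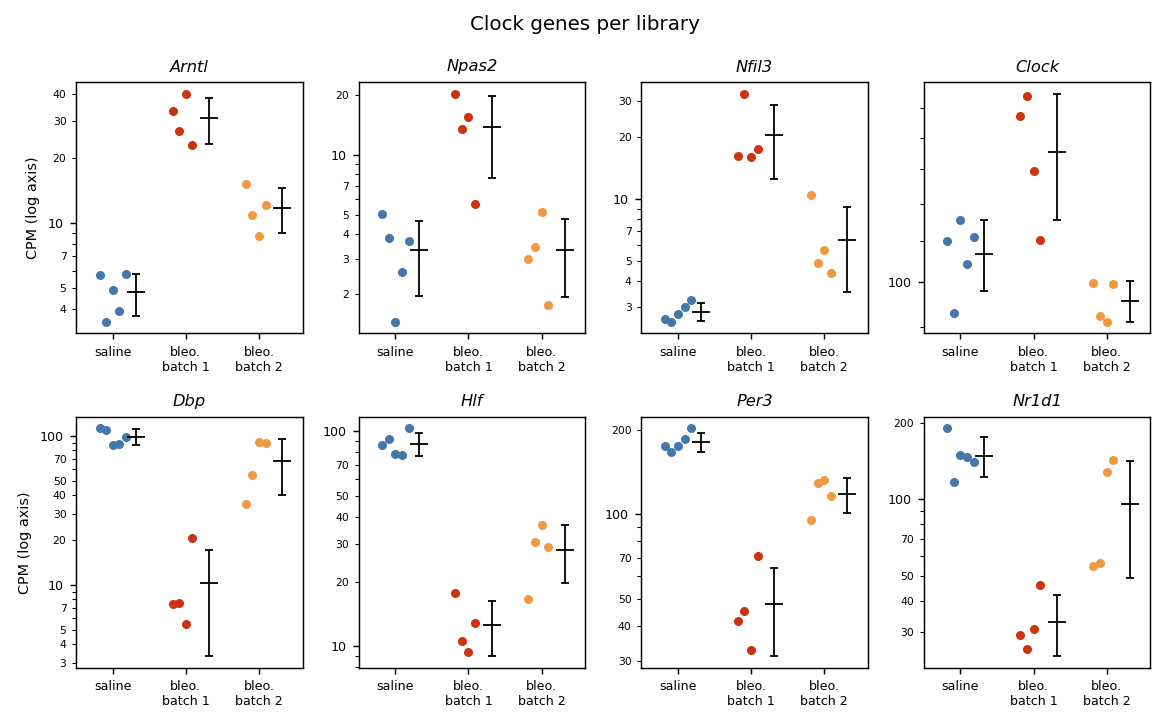
CPM of 8 clock genes (log axis) in each saline (blue), batch 1 bleomycin (red) and batch 2 bleomycin (orange) library, with the mean ± SD of each set in black. Arntl and Nfil3 are highest and Dbp, Hlf, Per3 and Nr1d1 lowest in batch 1 bleomycin, with the batch 2 means of these 6 genes between batch 1 bleomycin and saline.

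The last comparison asks whether gene groups moved together across the 8 bleomycin libraries. Libraries with more matrix expression had less alveolar expression. The matrix level, centred within batch, fell with the alveolar type 2 level (r = -0.955, adjusted p = 0.00182; rho = -0.905, adjusted p = 0.0106) and the alveolar type 1 level (r = -0.932, adjusted p = 0.00217; rho = -0.952, adjusted p = 0.00799) in exact permutation over 40320 pairings, n = 8. These pairings exchange libraries across batches although levels were centred within batch. Exchanged within batch only, an alternative chosen after the data were seen, 576 pairings gave the 5 relations that passed an exact adjusted p of 0.0162 to 0.0292 (rho 0.0243 to 0.0365). It also fell with the aerocyte level (r = -0.897, exact adjusted p = 0.00535; rho = -0.833, adjusted p = 0.0215). It rose with scar-associated macrophage genes (r = 0.965, exact adjusted p = 0.00182; rho = 0.905, adjusted p = 0.0106) and transitional epithelium (r = 0.930, exact adjusted p = 0.00217; rho = 0.833, adjusted p = 0.0215). Of the 7 relations computed, those with the general capillary list (r = -0.685, exact permutation p = 0.0563, adjusted p = 0.0657; rho = -0.405, adjusted p = 0.36) and the plasma cell list (r = 0.397, exact permutation p = 0.333, adjusted p = 0.333; rho = 0.381, adjusted p = 0.36) did not pass. The unadjusted exact permutation p-values of the 5 that passed were 0.000372 (scar-associated macrophage), 0.000521 (type 2), 0.00119 (type 1), 0.00124 (transitional epithelium) and 0.00382 (aerocyte) for r, and 0.00114 to 0.0154 for rho. Without the 2 libraries farthest from the median matrix level, bleomycin replicates 5 and 1, only the relation with type 1 passed (r = -0.989, exact adjusted p = 0.00972). The type 2 (r = -0.839), aerocyte (r = -0.842) and scar-associated macrophage (r = 0.888) relations then had an exact adjusted p = 0.0705, and transitional epithelium gave r = 0.592 (exact adjusted p = 0.241). Each batch holds 4 bleomycin libraries, too few for a correlation within a batch; uncentred, the type 1 relation did not pass (r = -0.731, exact adjusted p = 0.0514) where its rho did (-0.81, exact adjusted p = 0.0381).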

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

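The test of short RNAs of all classes was chosen only after the result was seen. Short non-coding RNAs of 6 classes were lower in bleomycin libraries, but microRNA genes had a median log2 change of -0.17 (95% interval -0.44 to 0.17, 46 genes), over the bound of -0.5 that a lower recovery of short RNAs of all classes would need. Their median level was 0.653 CPM, too near the floor to exclude this technical explanation, which stays open. Leaving out saline replicate 2, the library with the highest share of these RNAs, left 68.6% of the tested genes (432 of 630) lower, which argues against that library alone as the cause. Protein-coding genes with a longest transcript under 500 bases had a median of -0.47 (95% interval -1.02 to -0.19, 49 genes) against 0.06 in other protein-coding genes, near the bound of -0.50 set for this test, so a loss of short transcripts in general stays open. A biological fall of these RNAs after bleomycin was not tested and also stays open.

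The values below are libraries that lay far from the others of their treatment group. Each is given as the gap to the nearest other library divided by the group's whole range, in log2 CPM for lists and genes. Chance gives such a library in about 1 in 20 groups, and it was seen in 5 of 92 tests of list levels (5.43%), 2 of 20 of library measures (10.0%) and 27 of 496 of named genes (5.44%).

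Among lists, bleomycin replicate 1 was low for smooth muscle (0.564), T and NK cells (0.61) and heart muscle (0.559), bleomycin replicate 5 was high for general capillaries (0.571), and saline replicate 4 was low for alveolar fibroblasts (0.801). Mitochondrial messenger RNA took 2.53% of counts in bleomycin replicate 5 (0.751), and short non-coding RNA took 9.45% in saline replicate 2 (0.763).

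Among genes of bleomycin libraries, replicate 1 was low for the muscle genes Cnn1 (0.571), Synpo2 (0.551) and Ttn (0.536). Replicate 3 was high for Scgb1a1 (0.562), and replicate 6 was low for Tmem132d (0.598). Replicate 5 was high for Fibin (0.631) and mt-Co1 (0.579) and low for Krt17 (0.559), and replicate 8 was low for the type 1 gene Hopx (0.756) and the desaturase gene Scd2 (0.581).

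Among genes of saline libraries, replicate 1 was high for Cdkn2b (0.787) and low for Pxdc1 (0.775) and Hspa5 (0.748). Replicate 2 was high for Cd34 (0.784), Comp (0.801) and Rn7s2 (0.798) and low for Mmp12 (0.812), Myh4 (0.718), Krt4 (0.752) and Krt13 (0.783). Replicate 3 was high for Car4 (0.765) and low for Cemip (0.779) and Cma1 (0.736). Replicate 4 was low for Adamts4 (0.951) and Tppp3 (0.842), and replicate 5 was low for Upk3b (0.729) and Cxcl13 (0.811). The low values of Adamts4, Mmp12 and Myh4 were counts of 0, where the log scale widens the gap. The other saline libraries held only 6 to 21 counts of Adamts4, so its gap rests on values near the floor.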

How the results depend on the processing

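The fits of protein-coding genes alone and of halved counts and the tests with pairings exchanged within batch only were chosen only after the data were seen. The number of genes changed by treatment was 6319, and 4747 to 6966 under the alternatives other than the fold threshold, single libraries left out and the move of bleomycin replicate 8 to saline (DESeq2 6945, limma-voom 6966, no low-count filter 5834, protein-coding genes only 4897). Leaving out single libraries gave 5123 to 6546 genes (2863 to 3757 higher, 2119 to 2897 lower). With bleomycin replicate 8 moved to saline, 645 genes passed (399 higher, 246 lower), 598 of them shared with the 6319, and 0 of 46 list levels passed by exact permutation against 30; that move puts a library with high Fn1 among the controls. A threshold of 2-fold, which can only remove genes, left 3036 (1603 higher, 1433 lower). Of 100 splits of the batch 1 libraries, drawn from 126, only the real 1 gave as many genes (6319, with 2988 the highest other). This argues against chance for the gene count. Splits that keep 1 to 3 of the 4 bleomycin labels put both treatments in each group and gave 0 genes. Those that keep 0 gave 1573 to 2988, so the splits are no clean test of chance for genes either. For lists 18 of 100 splits gave at least the real 32 (37 the highest other), so chance is not excluded for the number of lists. All the others of these 18 keep 0, 1 or 3 of the 4 bleomycin labels. They therefore carry much of the real contrast or its reverse and are no clean test of chance. Splits that keep 2 of the labels gave 2 to 24 lists.

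The number of genes that differed by batch was 343, and 737 by DESeq2, 983 by limma-voom, 79 among protein-coding genes only and 224 with a threshold of 2-fold. Leaving out single libraries gave 148 to 1093: 534 without bleomycin replicate 1, 165 without replicate 2, 148 without replicate 3, 183 without replicate 4, 187 without replicate 6, 197 without replicate 7 and 1093 without replicate 8. Of the 35 splits of the 8 bleomycin libraries, 2 gave as many genes, the real one and that of replicates 1, 6, 7 and 8 against 2, 3, 4 and 5 with 660. That split exchanges only replicates 1 and 5 of the real one, so it carries much of the real contrast. Chance is not excluded for this count. Camera with an estimated correlation called 0 of 46 lists in place of 32, against 30 by fry. List calls were 29 to 35 under all other alternatives, with 32 to 34 when single libraries were left out, and exact permutation of levels passed 29 to 31 when batch 1 libraries were left out. Of the 5 relations, 1 passed without the 2 libraries farthest from the median matrix level, 4 without centring, 5 without bleomycin replicate 8 and 5 with pairings exchanged within batch only.

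Bleomycin and saline replicates share only a number: residual correlations between equal numbers were -0.349 to 0.0406, and the own number was the best partner in 1 of 5, so the comparisons were not paired. The replicate block, which takes the place of batch, gave 4747 genes (2588 higher, 2159 lower), 3883 shared and 3 of those in the opposite direction, and 29 lists. It compares bleomycin with saline replicates 1 to 5, since bleomycin replicates 6 to 8 have no saline partner. Bleomycin replicates 1 to 4 are of batch 2, so this fit mixes batch with treatment. Under the replicate block the sign turned for alveolar type 2 (0.07), heart muscle (-0.251), cartilage (0.449), Myh7 (-0.556), Hapln1 (0.361), Ager (0.071), n-R5s195 (0.659), Rn7s2 (1.309), Rn7s1 (0.474), Ryr2 (-0.023), mt-Rnr2 (0.681) and Clock (-0.029).

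Other turns of sign were as follows, and the cause was not tested. Without the batch term they were pericyte (-0.006), resident alveolar macrophage (0.021), cartilage (0.363), n-R5s195 (0.205), Rn7s2 (1.039), Rn7s1 (0.138) and mt-Rnr2 (0.429). With bleomycin replicate 8 moved to saline they were mast cell, eosinophil and basophil (-0.62), cartilage (0.097), Saa3 (-0.136), Cma1 (-0.277), Cfd (-0.791) and mt-Co1 (0.297). The pericyte median, 0.01 in the main comparison, was -0.032 with RLE size factors, -0.028 with mitochondrial, haemoglobin and immunoglobulin genes removed, -0.023 in batch 1 only, -0.044 with protein-coding genes only, -0.001 with counts halved and -0.033 with genes of more than 1 list removed. The last gave 0.239 for resident alveolar macrophages. Cartilage was 0.349 with no low-count filter, 0.264 with protein-coding genes only and 0.346 with counts halved. By limma-voom Hapln1 was 0.392, Ryr2 -0.387, Cfd -0.123 and Acan 1.225, and Acan was 0.114 on the deposited normalized table.

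With single libraries left out, list medians that turned ranged over -0.065 to 0.096 for pericyte, -0.801 to 0.346 for mast cell, eosinophil and basophil, -0.1 to 0.171 for nuclear oxidative phosphorylation, -0.661 to 0.77 for heart muscle and -0.355 to 0.505 for cartilage. Genes that turned without bleomycin replicate 5 ranged over -0.025 to 0.346 (Hdc), -0.061 to 2.44 (Pln) and -0.524 to 0.825 (Ryr2). Those that turned without saline replicate 2 ranged over -1.109 to 0.351 (Hapln1) and -1.264 to 0.343 (Acan). Cfd, which turned without bleomycin replicate 8, ranged over -0.365 to 0.725, and Per1, which turned without bleomycin replicate 7, over -0.137 to 0.04. Ranges were -0.333 to 0.098 for mt-Rnr2 and -0.593 to 0.134 for mt-Co1. None of these lists and genes was called in the main comparison except alveolar type 2, Saa3, Ager, n-R5s195, Rn7s2, Rn7s1 and Clock. Over all alternatives, named genes kept their direction and call in 6204 cases, lost the call in 432, gained it in 35 and turned in 38, and lists did so in 1096, 44, 14 and 39. Small changes can be missed, since simulated changes of 1.5-fold were recovered for 10.4% of genes. Halving the counts gave 6379 calls, and lower depths were not tested.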

Other observations

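The tests of the clock and mitochondrial patterns were chosen only after the results were seen. The 12 largest falls among protein-coding genes outside the mitochondrial genome, a set chosen after its values were seen and with no test of a shared theme, were those of Ankrd63, Bex2, Tmem132d, Dbp, Abca12, Gria1, Hlf, Ttyh1, Cyp2a5, Atp2b2, Inmt and Vpreb3. Abca12 had the highest adjusted p of the 12 and a wide spread in saline (25.3 ± 17.4 to 3.11 ± 2.06 CPM, -3.03, SE 0.97, adjusted p = 0.0373 in edgeR). Among saline libraries it was highest in replicates 4, 5 and 1 (48.3, 37.6 and 22.1 CPM), as was the oesophageal keratin gene Krt13. Saline replicate 2, however, held 11.3 CPM of Abca12 at 0.12 CPM of Krt13. A shared source was not tested, so the fall of Abca12 is uncertain. The fall of Ttyh1 is uncertain, since its saline counts ran in the same order as those of mt-Tg. Bex2 went from 13.3 ± 2.94 to 1.16 ± 0.51 CPM, Tmem132d from 15.6 ± 3.48 to 1.37 ± 1.20 CPM, the glutamate receptor gene Gria1 from 29.3 ± 3.29 to 3.96 ± 2.98 CPM and the calcium pump gene Atp2b2 from 17.9 ± 3.09 to 2.81 ± 1.67 CPM. In batch 2 bleomycin Tmem132d, Gria1 and Atp2b2 stood at 2.59 ± 0.61, 4.31 ± 2.85 and 9.66 ± 5.52 CPM. Vpreb3, a gene of B cell precursors, also fell (13.5 ± 2.75 to 2.53 ± 1.30 CPM) while the B cell list rose.

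Immunoglobulin segments, which the naming rule left out and which were looked at after their values were seen, rose with the plasma cell list. That list holds Igha, which is also counted among the segments, so these results are not independent. Of 127 tested segments 92 were higher and 0 lower in edgeR, with a median log2 change of 4.18. Immunoglobulin genes took 0.0114 ± 0.0064% of counts in saline, 0.179 ± 0.126% in batch 1 bleomycin and 0.178 ± 0.076% in batch 2.

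Clock genes differed between bleomycin and saline libraries of batch 1. An index over 14 of the 16, without Dbp and Nr1d1, which led to the others by their batch difference, was the mean log2 CPM of Arntl, Npas2, Clock, Nfil3 and Cry1 minus that of the 9 others. It differed between batch 2 and batch 1 bleomycin (-1.82, exact permutation p = 0.0286, the smallest its 70 splits allow) while the matrix level differed by -0.03. The alveolar type 2 level differed by 0.54, not past chance (exact permutation p = 0.171) but just over its SD of 0.50 in batch 1 and 0.52 in batch 2. The extent of injury therefore stays open. The batch 2 mean lay between the other means for 14 of the 16 genes, Dbp and Nr1d1 among the 16, which milder injury, a drug effect or time of day at collection would each give. Collection times are not in the labels, so the extent of fibrosis, time of day and an effect of bleomycin on the clock cannot be told apart.

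Several mitochondrial genes were near 0 in batch 2 bleomycin. Reads shared with near-identical nuclear copies may be the source for mt-Co2, mt-Atp6, mt-Co3 and mt-Nd4l, with over 90% of their sequence in nuclear transcripts. But mt-Atp8 (batch adjusted p = 0.0105) and the transfer RNA mt-Tg (0.0131) also fell with 0% shared. Mt-Nd3 has 98% shared and a fall of less than 1. Of 9 mitochondrial genes near 0 in batch 2, 4 had over 90% shared and 5 under 10%. Only annotated nuclear transcripts were searched, so copies outside them count as 0% shared. A low share therefore does not exclude shared reads. Over all tested mitochondrial genes, the 5 with over 90% shared changed by -4.43 on average and the 27 with under 10% by -1.31 (difference -3.11, exact permutation p = 0.0607 over 201376 splits of genes, which are not independent replicates), so this stays open. A fall of all mitochondrial messenger RNAs large enough to bring counts near 0 is argued against by a median change of -0.69 in the 6 with under 10% shared, although a smaller fall is not excluded. No biological explanation was tested, because both batches hold bleomycin libraries.

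The 18S ribosomal RNA gene Rn18s-rs5 took 3.91% to 21.3% of counts in bleomycin libraries and 5.30% to 13.5% in saline. The oesophageal keratin gene Krt13 ranged from 0 to 643 CPM in bleomycin libraries.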
